A study of Arabidopsis thaliana with 3 samples.

How the data were processed

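The series holds 3 two-colour cDNA microarrays of Arabidopsis thaliana, called set 1, set 2 and set 3. Per the labels, total RNA of wild-type inflorescences was channel 1 and total RNA of apetala3 inflorescences was channel 2 on every array. A cDNA array carries amplified cDNA inserts spotted on glass, and both RNAs compete for the same spot, so each spot gives a ratio and not an absolute level. The arrays formed 1 group of 3, with the set numbers taken from the labels.

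The deposited table had 9019 features with 1 value per feature and array and 0 missing values. The authors preprocessed and normalized the values before deposit, per the labels, which cite a publication for the procedure. The background correction, normalization method, spot filters, dyes, scanner settings and software are not given in the sources used here. Nor is it given whether the value of a set already averages hybridizations, such as a pair with swapped dyes, so each set was counted as 1 replicate. The deposited values were taken as log2 ratios of the channels, from the values themselves. After multiplication by the natural log of 2, 98.8% of the 27057 values were whole multiples of 0.0001 within 0.01 of a step, where 2% would be by chance. This is the pattern of rounded natural-log ratios that were converted to log2. Multiplication by log10 of 2 gave 2.17%. The last of the 7 printed decimals was a 3 in every value and carries no information. The array medians were -0.13, -0.11 and -0.11, so the values were not centred on the median of the features held here. The channel used as the numerator is not given in the sources used here, and no direction between mutant and wild type was assigned to the sign. Scanner intensities were not analysed here, so signal over background and saturation per spot are unknown. The stated precision rests only on the number of arrays and the spread between them.

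Feature identifiers were read as a plate and a well (GP085C12 as plate 85, row C, column 12), since they use 8 row letters and 12 column numbers. They cover 114 plates with 22 to 93 features each. None of them (0) stood in the reference gene table, and the table does not pair them with genes. The features are therefore reported by identifier, with no genomic position. The 12 gene lists (273 genes) chosen before the data were examined, among them tapetum, pollen, petal, carpel and photosynthesis genes, were not tested. Several features can stand for the same gene, so counts of features are not counts of genes.

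The mean log2 ratio of each feature was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, then eBayes, two-sided), on the deposited values with no filter. P-values were adjusted by Benjamini-Hochberg over all 9019 features, and a call is an adjusted p under 0.05. Each ratio already pairs mutant with wild type on its array. The rule for named features, set before the data were examined, was the 2 largest mean ratios on each side among calls with the same sign on all 3 arrays, since the rows could not be named by gene. Nothing in the labels says whether the sets came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

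The test was checked on simulated data of 9019 features on 3 arrays, in 5 runs with 200 changed features each and the spread that limma estimated from the real arrays. It recovered 5.2% of features changed by 0.5 on the log2 scale, 83.6% of those changed by 1, 98.8% of those changed by 2 and 100% of those changed by 4. Of all calls, 4.39% were on unchanged features. The simulation changed far fewer features than the 3473 called on the real arrays, so its Benjamini-Hochberg cut was stricter. The recovered shares therefore do not give the sensitivity of the real test, which called more of the small differences. Because the simulated errors followed limma's own variance model, the share of false calls checks the procedure and not the real arrays.

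The alternatives set before the data were examined were median centring, scaling to one median absolute deviation, a robust variance prior, array weights, a 2-fold threshold, a 2-fold rule without a model, other log bases, and leaving out each array. Centring on the mode (the peak of each array's density) and the comparisons between plates were added after the data were seen. Descriptions and plate tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.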

Results

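Gene expression in inflorescences of the apetala3 mutant was compared with that in wild-type inflorescences on 3 two-colour cDNA arrays. APETALA3 encodes a MADS-box transcription factor required for petal and stamen identity. Strong mutants form sepals in place of petals and carpels in place of stamens, so that a wild-type inflorescence contains petals, stamens and pollen that such mutants lack. The comparison addresses which transcripts depend on the organs specified by APETALA3. Each of the 9019 features was measured on all 3 arrays as a normalised log2 ratio of mutant and wild-type RNA. The features are given by plate and well, as the values are not paired with gene names. The numerator of the ratio is not stated, so the results are given as negative and positive log2 ratios, and the same side means the same direction on all arrays.

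A large group of features had log2 ratios far from 0, and almost all of these large ratios lay on the negative side. On set 1, 2231 features (24.7%) had a log2 ratio at or below -1, which is a difference of at least 2-fold, and 82 (0.909%) had a ratio at or above 1. Set 2 had 2165 (24.0%) and 53 (0.588%) such features, and set 3 had 2017 (22.4%) and 37 (0.410%). The ratios reached -5.96, -5.28 and -6.35 at the negative end of sets 1, 2 and 3, and 2.22, 1.85 and 2.19 at the positive end. The distribution was bimodal on every array. The main peak lay close to 0, with modes at -0.01, 0.04 and 0.04, and a second, broad hump lay between about -3 and -4 on each array. Of the feature means, 1182 were at or below -3, against 896 between -3 and -1.

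**Figure D1:**
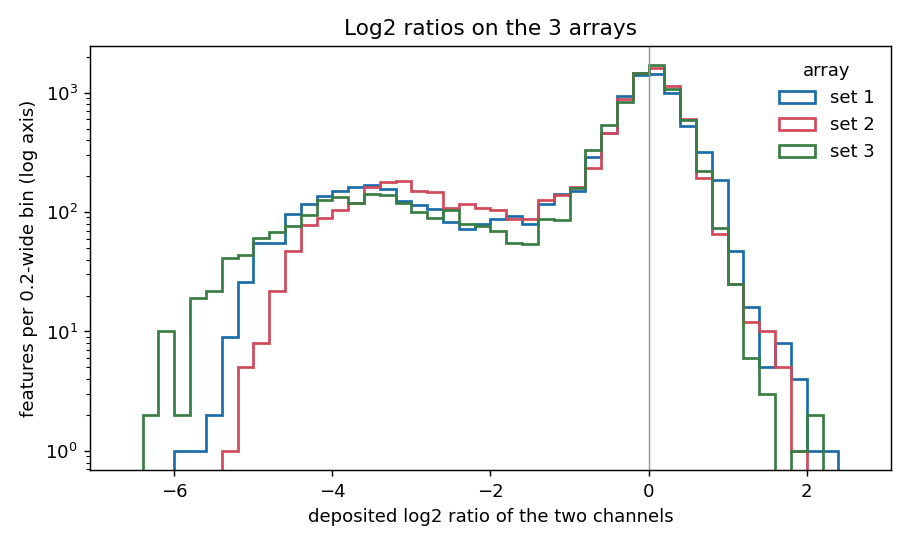
Histogram of the deposited log2 ratios of the 9019 features, with 1 outline for each of the 3 arrays; the x axis is the log2 ratio of the channels and the y axis the number of features per bin of 0.2 on a log scale. Each array has a main peak close to 0 and a second hump on the negative side, reaching -5.96, -5.28 and -6.35 on sets 1, 2 and 3, with no such hump on the positive side.

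The 3 arrays ran in the same direction and ranked the features alike. Across features, which are not independent replicates, Pearson's r was 0.968 between sets 1 and 2, 0.959 between sets 1 and 3 and 0.955 between sets 2 and 3. Spearman's rho was 0.810, 0.799 and 0.793. The agreement rested in part on the large negative ratios. Among the 6916 features with a mean between -1 and 1, Pearson's r was 0.654, 0.570 and 0.577. All 3 arrays gave the same sign for 5762 features (63.9%). The share would be 25% if signs were independent between arrays and equally often negative and positive. Errors shared by the arrays would raise it without any difference between the RNAs. The median SD between arrays was 0.220 on the log2 scale over all features. It was 0.187 for features with a mean between -0.5 and 0.5 and 0.388 for those at or below -3. The sets differed in the size of the largest ratios. Features with a mean at or below -3 averaged -3.93 on set 1, -3.51 on set 2 and -4.05 on set 3, and those with a mean above 0.5 averaged 0.810, 0.634 and 0.612.

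**Figure D2:**
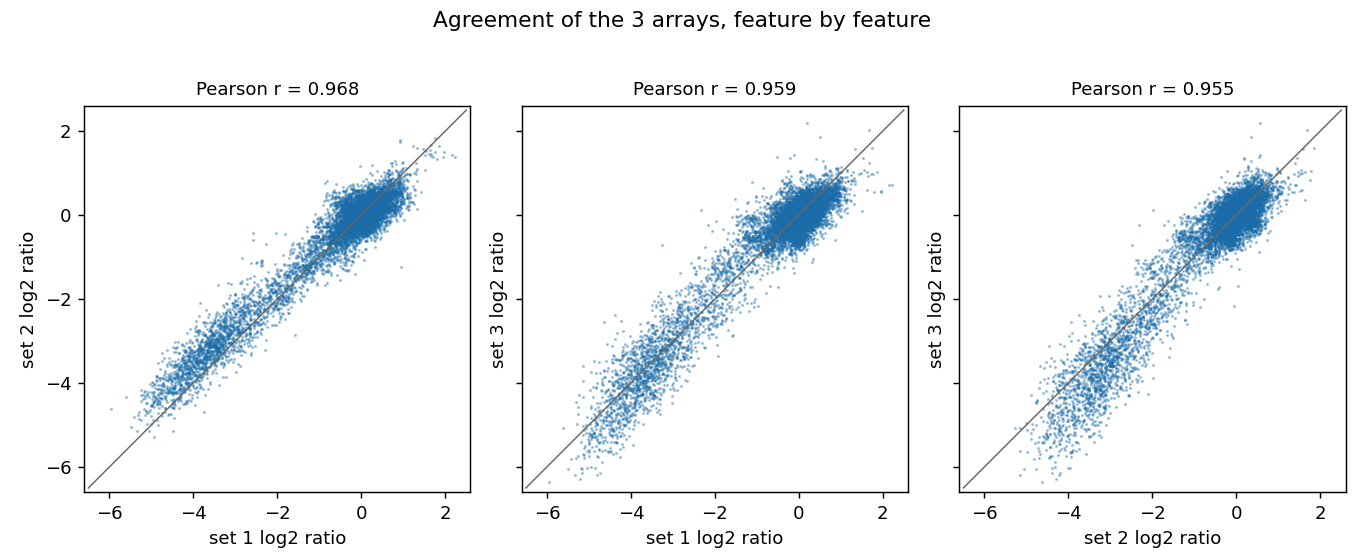
Log2 ratio of each feature on a pair of arrays, with 1 panel per pair, both axes in log2 units and the line marking equal values. Pearson's r across features is 0.968, 0.959 and 0.955, and the points at the negative end lie above the line in the panel of sets 1 and 2 and below it in the panel of sets 2 and 3.

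In limma's test of the mean log2 ratio against 0, 3473 of the 9019 features (38.5%) passed an adjusted p of 0.05, and 2774 of these calls were negative and 699 positive. The same sign was seen on all 3 arrays for 3471 of the calls. The 2 sides differed in size more than in number. At least 2-fold differences made up 2078 of the negative calls (74.9%) and 25 of the positive calls (3.58%). At least 4-fold differences were found for 1668 negative and 0 positive calls, at least 8-fold differences for 1182 negative calls, at least 16-fold differences for 413 and at least 32-fold differences for 31. The largest positive mean was 1.79, so 0 positive means reached 4-fold with or without the test. A further 5546 features did not pass, and the smallest mean ratio among the calls was 0.364 in size, so no smaller difference was called with 3 arrays.

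The largest negative mean was that of feature GP085C12, with log2 ratios of -5.96, -4.62 and -6.35 on sets 1 to 3 and a mean of -5.64 ± 0.908 (SD, n = 3), a 49.9-fold difference (limma, adjusted p = 2.312e-06). It was followed by GP066F3, with a mean of -5.56 ± 0.552 (SD, n = 3), a 47.2-fold difference (limma, adjusted p = 7.174e-07). Their difference from each other was smaller than the spread between arrays. The largest positive mean was that of GP139B11, with 1.67, 1.67 and 2.04 on sets 1 to 3 and a mean of 1.79 ± 0.212 (SD, n = 3), a 3.46-fold difference (limma, adjusted p = 1.653e-05). GP079D10 followed with a mean of 1.73 ± 0.128 (SD, n = 3), a 3.31-fold difference (limma, adjusted p = 1.284e-05).

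The split between the sides changed with the zero point and when an array was left out. The calls were 79.9% negative on the deposited values and 67.9% negative after each array was centred on its median, which raised every ratio by 0.107 to 0.128 and gave 1204 positive calls. Centring on the mode, added after the data were seen, left them 82.05% negative, with 621 positive calls. There were 223 positive calls without set 1, 414 without set 2 and 515 without set 3, beside 2405, 2467 and 2691 negative calls. The 25 positive calls of at least 2-fold became 53 after median centring and 42 without set 3, and stayed at 25 after mode centring.

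The plates on which the features were kept differed in their share of large negative ratios, and the calls were therefore also counted by plate, over the plates before the last gap in the plate numbers (0 to 45) and, after it, the plates on either side of the sharpest change in that share (55 to 118 and 119 to 147), a division chosen after the values were seen. Plates 55 to 118 held 5470 features, of which 1758 (32.1%) had a mean log2 ratio at or below -1. Plates 119 to 147 held 2215 features, of which 102 (4.61%) did, and plates 0 to 45 held 1334, of which 218 (16.3%) did. The share on single plates ran from 19.6% to 44.3% in plates 55 to 118, from 1.28% to 8.97% in plates 119 to 147 and from 0% to 38.3% in plates 0 to 45. Set by set, the share was 34.0%, 33.2% and 31.3% in plates 55 to 118 and 5.42%, 5.19% and 4.24% in plates 119 to 147. Over all 114 plates the SD of the share was 13.8 percentage points, and the highest SD in 10000 shuffles of the features over the plates was 6.36 (permutation test, one-sided, p = 0.0001, the smallest these shuffles can give). The balance of negative and positive calls differed between the runs of plates. There were 2210 negative and 337 positive calls in plates 55 to 118, 351 and 147 in plates 0 to 45, and 213 and 215 in plates 119 to 147. In plates 119 to 147 this balance depended on the setting. Median centring gave 179 negative and 425 positive calls. Leaving out an array gave 148 and 55 without set 1, 163 and 90 without set 2, and 206 and 136 without set 3. Scaling and the robust variance prior each gave 213 and 212, array weights 217 and 222, and mode centring 228 and 186. In plates 55 to 118 negative calls were the more numerous under all of these settings, by 3.74 to 21.6 times, with 551 positive calls after median centring, 91 without set 1 and 219 without set 2. In plates 0 to 45 negative calls were also the more numerous, by 1.38 times after median centring (228 positive calls) to 3.74 times without set 1 (77 positive calls). At least 2-fold calls in plates 119 to 147 were still mostly negative, with 102 negative and 6 positive. The arrays agreed within each run of plates. Pearson's r between arrays was 0.972, 0.961 and 0.958 in plates 55 to 118, 0.898, 0.899 and 0.883 in plates 119 to 147, and 0.956, 0.944 and 0.942 in plates 0 to 45, for sets 1 and 2, sets 1 and 3 and sets 2 and 3. By position within a plate, the share at or below -1 was 21.9% to 23.7% over the 8 well rows and 21.0% to 26.6% over the 12 well columns.

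**Figure D3:**
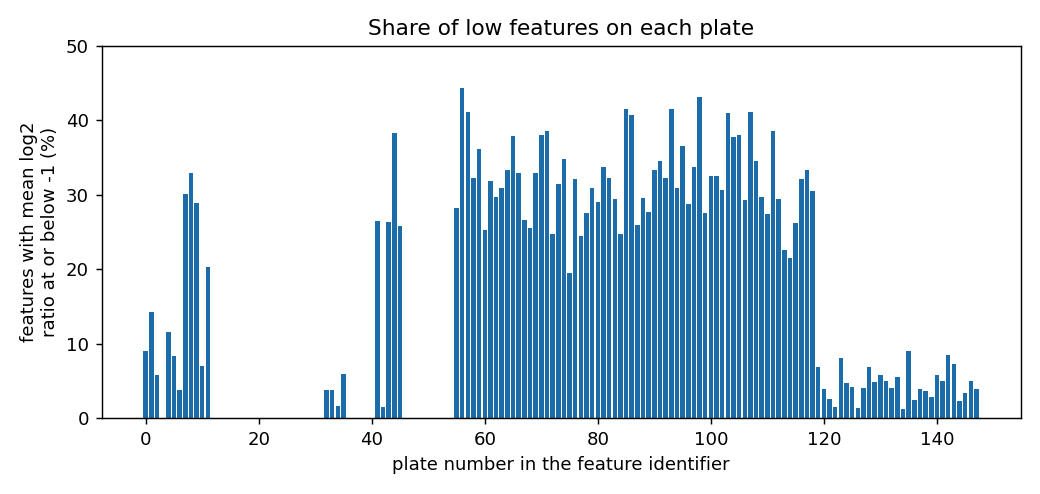
Percentage of the features on each of 114 plates with a mean log2 ratio at or below -1 (y axis), by the plate number in the feature identifier (x axis), with 1 bar per plate and gaps where the table has no plate of that number. The bars of plates 55 to 118 stand between 19.6% and 44.3%, and those of plates 119 to 147 between 1.28% and 8.97%.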

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

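The number of calls stayed within 1.5 times of 3473 under median centring (3756), scaling (3443), the robust variance prior (3459), array weights (3492) and mode centring (3459, added after the data were seen), and ranged from 2628 to 3206 when an array was left out. The calls shared with the deposited values, sign included, were 3251, 3438, 3459, 3455 and 3395 in that order. A 2-fold threshold beside the adjusted p left 2103 calls, and at least 2-fold on every array, without a model, left 1950, of which 9 were positive; both are lower because they demand more. Positive calls numbered 1204 under median centring, 621 under mode centring and 223 to 515 when an array was left out. Positive calls of at least 2-fold numbered 53 under median centring, 25 under mode centring and 28 to 42 when an array was left out, where 42 came without set 3. Read as log10 or natural logs, the values would give 699 or 160 positive calls of at least 2-fold. Negative calls ranged from 2405 to 2691 and those of at least 2-fold from 2034 to 2170 when an array was left out. Median centring adds a constant to each array. Leaving out an array gives the test fewer values per feature, so small differences are harder to call, and 3.58% of positive calls reached 2-fold. How far this explains the fewer positive calls, and the cause of the other moves, was not tested. The 4 named features kept their sign and an adjusted p under 0.05 in all 8 refits of limma, where the highest adjusted p was 0.0006121, for GP079D10 without set 1. These features were chosen for the largest means on the same arrays, so this is no independent support for them. No paired analysis was possible because each ratio already pairs the RNAs within its array and the series has 1 group. The alternatives on missing values, features of one gene, dim features, opposite array signs and gene lists were not run: no value was missing, no array ran the opposite way, and the table gives neither gene names nor intensities. Turning the sign of each array in turn gave 0 calls at the highest against the real 3473 (1 of 4 sign patterns as large), and 4 patterns are too few for a share under 0.05. The absence of intensities leaves open how far background limits the largest ratios.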

Other observations

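The tests of plates and wells, the 8-fold count and the look at dye orientation below were chosen only after the results they bear on were seen, whereas median centring was among the alternatives set beforehand; no biological explanation of the plate pattern was tested, as the labels do not say which clones the plates hold.

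Positive calls of at least 2-fold were unevenly spread over the plates, although the 2 largest positive means (GP139B11 and GP079D10) lay on plates 139 and 79. Of the 25 positive calls of at least 2-fold, 18 (72%) lay on plates 0 to 45, which hold 14.8% of the features, and 7 lay on the other plates (1.35% of 1334 features against 0.0911% of 7685; Fisher's exact test, two-sided, p = 1.76e-10, with features taken as independent). They came from 9 plates, with 6 on plate 3, and 12 remain without that plate. Of the 9 features at least 2-fold positive on every array, 5 lay on plates 0 to 45 and the others elsewhere. Among the 18, 5 pairs sat in neighbouring wells of a row, against a mean of 0.52 and a maximum of 4 in 10000 random placements on the same plates (permutation test, one-sided, p = 0.0001, the smallest these placements can give). All of these pairs lay on plates 2 and 3, and the other plates with such calls gave none. The same clone, or the same gene, in neighbouring wells may therefore account for part of this gathering, and the Fisher test then overstates it. The 4 such calls on plate 2 averaged 2.07, 1.43 and 0.64 on sets 1 to 3, and the 6 on plate 3 averaged 1.59, 1.46 and 1.03, so set 3 gave the smallest average on both plates. Pairs outside these calls were not counted, so likeness of neighbours need not be confined to plates 2 and 3. On plate 1, an example picked by eye was GP001E9 (-2.49, -1.12 and -1.23 on sets 1 to 3) beside GP001E10 (-2.37, -1.11 and -1.21). Other neighbours there differed, such as GP001D10 with a mean of -1.26 and GP001D11 with -0.257. Over all features, the mean ratios of neighbouring wells of a row correlated with r = 0.185 on plates 0 to 45 (913 pairs, across features; permutation test with 1000 shuffles within plates, one-sided, p = 0.02, 0.07 after Benjamini-Hochberg adjustment over the 3 runs of plates). The shuffles there gave r from 0.00497 to 0.22, since they keep the differences between plates, so 0.185 is not all likeness of neighbours. In the same permutation test, r was 0.022 on plates 55 to 118 (p = 0.1, adjusted 0.2) and -0.00129 on plates 119 to 147 (p = 0.4, adjusted 0.4). Carry-over between wells would also make neighbours alike, and these correlations do not separate it from repeats of a clone. The 4 positive calls of at least 2-fold on plate 2 were GP002D2, GP002D3, GP002D11 and GP002D12. Each was highest on set 1 and lowest on set 3, with averages of 2.07, 1.43 and 0.64. The wells measured between GP002D3 and GP002D11 gave no such call. This argues against carry-over between neighbours as the whole cause of the likeness of these 4. Carry-over within a pair, and on the other plates, stays open.

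The contrast between plates 55 to 118 and plates 119 to 147 is a pattern for which 2 simple technical explanations were set against the values. A single offset for all features of a plate would move every percentile alike. The 10th percentile lay 3.26 higher on plates 119 to 147 (95% interval 3.17 to 3.36 over 1000 resamples of plates) and the 90th only 0.0892 higher (0.0601 to 0.127), a difference of 3.17 that argues against an offset as the whole cause. These intervals hold the boundary between the runs fixed, although it was chosen from the same values. Compression of the ratios on plates 119 to 147 by a common factor would shrink both ends alike. The ratio of the 95th percentiles was 1.06 and that of the 4th percentiles 0.296, a difference of 0.763 (0.658 to 0.862), which argues against a common factor as the whole cause. The 4th percentile of plates 119 to 147 (-1.257) lies at the edge of their 4.61% of low features, so its ratio also reflects that smaller share. A weaker compression beside a difference in share stays open. Low features had a median of -2.435 on plates 119 to 147 and -3.248 on plates 55 to 118. Compression that acts mainly on large ratios stays open. The 95th percentiles (0.474 on plates 55 to 118 and 0.502 on plates 119 to 147) lie too close to 0 to show it. Whether a few clones recur many times on plates 55 to 118 stays open: 1419 pairs of their 1758 low features lay within 0.1 on every array, inside the range of 1409 to 1516 over 100 shuffles, but the spread between spots of one clone is not known here. A different clone content, such as another source library, is a candidate explanation that these values leave open. The contrast of 27.5 percentage points stayed between 27.0 and 28.0 under each centring, scaling and left-out array. The boundary between the runs was not chosen anew in these settings, so this stability is no independent support for the contrast.

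The imbalance between negative and positive ratios bears on the direction that the labels leave open. The array medians lay at only -0.128 to -0.107, so centring on them could hardly change the large ratios. After median centring there were still 38.1 negative calls of at least 2-fold for each positive one. A zero point off by that much does not account for the imbalance of large ratios. It does bear on the number of calls, with 2774 negative and 699 positive before median centring and 2552 and 1204 after it. Mode centring gave 2838 and 621. Whether the ratios are apetala3 over wild type, with transcripts of petals and stamens on the negative side, could not be tested. On every array, 908 features were at least 8-fold negative and 0 at least 8-fold positive, but this count restates the imbalance and decides nothing. The sign of features known to represent APETALA3, PISTILLATA or pollen genes would decide it, and no feature could be paired with a gene. A dye effect shared by all sets cannot be told apart from a genotype effect. The lowest correlation between sets was 0.955, so no deposited ratio runs the opposite way. This does not show the dye orientation, as a set with swapped dyes could be deposited as the same quotient of the RNAs. It is also not known whether each value already averages swapped dyes, in which case a dye effect would cancel.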
